A study of Mus musculus with 12 samples.

How the data were processed

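Liver RNA of 12 mice was prepared with a stranded poly(A) mRNA kit and sequenced as single reads of 100 bp, per the labels' protocols. The sample titles name primary murine hepatocytes, whereas the labels' protocols describe liver taken from mice injected in life; the text follows the protocols and says liver. Each group held 3 mice, so the replicates are separate animals. Reads were trimmed with Trim Galore 0.6.6-0, aligned to GRCm38 with STAR 2.7.6a and counted with HTSeq 0.12.4, per the submitters' processing notes. The strand setting and the annotation used for counting are not given in the sources used here. Reads from overlapping, antisense or near-identical genes can therefore not be told apart, which concerns the Acot, Cyp4a, Acaa1, Saa and Gbp families.

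The deposited values are whole-number read counts per gene, not normalised, in 48 files, 4 sequencing lanes for each of 12 libraries. No library held counts outside named genes. Counts of the 4 lanes of a library differed by little more than sampling noise (dispersion between 1.001 and 1.035 of that of Poisson counts over genes with at least 40 counts) and were summed. Replicate mice differed by far more, with a chi-square per gene between 13.55 and 120.93 for pairs of the same group, so no library was counted more than once. Totals ran from 8066422 to 14041353 counts per library. The limit given by 3 counts was between 0.214 and 0.372 CPM per library; such limits and count ratio intervals cover counting error only, since reads without molecular identifiers are not independent molecules. Of 55401 gene identifiers, 55141 were matched to GENCODE release 21 of the mouse annotation on GRCm38, which gave symbols and positions. Counts are per gene and resolve no exon or untranslated region.

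Genes were filtered with filterByExpr by group, which left 12753, and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 (robust, TMM scaling, two-sided), with all 12 libraries in 1 fit and group means as the design. The p-values were adjusted by the method of Benjamini and Hochberg over the genes tested in a comparison, and adjusted p below 0.05 was called. The 6 comparisons were GW vs DMSO, C29 vs DMSO, GW+C29 vs DMSO, GW+C29 vs GW, GW+C29 vs C29, and the interaction, which is GW+C29 vs C29 minus GW vs DMSO. CPM values, computed from the deposited counts, use TMM-scaled library sizes and are given as mean ± SD over the 3 libraries of a group. The test was run on simulated counts with 200 changed genes drawn from the means and library sizes of these libraries. Where a group had no counts of a gene, the fold is a lower bound against 3 counts over the group.

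Gene lists were fixed before the data were examined: 22 pathway lists and 15 lists of cell type markers. The pathway lists are peroxisomal and microsomal fatty acid oxidation, mitochondrial β-oxidation and ketogenesis, lipid droplets and fatty acid uptake, fasting hormone and fuel switch genes, gluconeogenesis, genes described as ERRα targets, nuclear encoded oxidative phosphorylation, citric acid cycle, mitochondrial genome transcripts, lipogenesis, cholesterol synthesis and uptake, bile acid synthesis and transport, inflammation and acute phase, xenobiotic metabolism, circadian clock, autophagy and lysosome, nuclear receptors and coregulators, glucocorticoid responsive genes, ATF4 and unfolded protein response, NRF2 and oxidative stress, amino acid catabolism and urea cycle, and cell cycle. The cell type lists cover hepatocytes, periportal and pericentral hepatocytes, Kupffer cells, sinusoidal endothelial cells, stellate cells and fibroblasts, cholangiocytes, T and NK cells, B cells, neutrophils, monocytes and dendritic cells, erythroid cells, adipocytes, mesothelial cells and skeletal muscle. Lists share members, such as Pck1, Pdk4, Acadm and Fabp1. Each list was tested with camera in limma 3.58.1 (preset correlation 0.01), adjusted over the 222 tests of 37 lists and 6 comparisons, and again with an estimated correlation. The self-contained test fry of limma, which asks whether a list moved without ranking it against other genes, was also run. Its values are given only for the fit without both DMSO 2 and GW 1, which was chosen after seeing the data. With the preset correlation 40 of 222 tests passed, and with the estimated correlation 0 did. The T and NK cell list had 1 of 9, the adipocyte list 2 of 6 and the mesothelial list 1 of 3 members tested.

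The genes named were set by a rule fixed before the data were examined. In each comparison it takes Esrra and Ppara, the 8 largest rises and the 8 largest falls among called genes with a mean of at least 2 CPM in the higher group and groups that do not overlap (leaving out predicted models and pseudogenes), and, from each pathway list, up to 4 called members by p and up to 2 members of highest CPM that did not pass; not every gene it takes is named here. Genes named outside it, because a count of 5 or fewer or a list rests on them or because another tool called them, were chosen after their values were seen: Serpina7, Trdn, Angptl4, Hspa5 and Pdk4 on C29 vs DMSO, Serpina7 on GW vs DMSO and GW+C29 vs C29, Serpina7, Acot1 and Acot2 in the interaction, Fabp1 on GW vs DMSO, Mfn2, Clock and Aass on GW+C29 vs C29, and the genes named beside counts of other settings.

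The alternatives tried were RLE and upper quartile scaling, DESeq2 1.42.0, limma-voom, no filter, a filter of at least 1 CPM in at least 3 libraries, the replicate number as a block, only the groups compared, lane 1 alone, and each of the 12 libraries left out in turn. After seeing the data, fits without DMSO 2 and GW 1, fits without DMSO 2 and GW 3, and a fit with the mean log2 CPM of the skeletal muscle list as a covariate were added. The slope of the response to C29 was to be taken over genes called on C29 vs DMSO; with 0 such genes it is given over all genes tested.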

Results

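RNA sequencing counts were obtained for 12 liver libraries from male C57Bl/6J mice aged 11 weeks, with 3 mice in each of 4 groups. After an overnight fast, mice were injected with solvent (the DMSO group), with GW7647 at 4 mg/kg (GW), with Compound 29 at 10 mg/kg (C29) or with both compounds (GW+C29), and tissue was taken 4 h later. GW7647 is an agonist of PPARα, the nuclear receptor that drives hepatic fatty acid oxidation in fasting. Compound 29 is an inverse agonist of ERRα (gene symbol Esrra), a nuclear receptor that controls mitochondrial genes. The comparisons ask what each compound does alone, and whether the response to GW differs when C29 is also given. Total counts were 8828773, 8066422 and 10450050 in DMSO 1 to DMSO 3, 14004149, 12534019 and 14041353 in GW, 11837404, 9283242 and 11697689 in C29, and 12335436, 10085255 and 8449471 in GW+C29. In these libraries 3 counts corresponded to between 0.214 and 0.372 CPM, the count scaled to library size. Of 55401 genes in the files, 12753 had enough counts to be tested.

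Markers of cell types other than hepatocytes set some libraries apart from the rest of their group. The summed level of skeletal muscle markers (Acta1, Ckm, Myh4 and Mylpf) was 467 CPM in DMSO 2, 209 CPM in GW 3, 40.6 CPM in GW 2 and 6.19 CPM in C29 3, against at most 1.98 CPM in the other 8 libraries. Kupffer cell markers, such as Clec4f and C1qa, summed to 1410 CPM in GW 1, and to between 196 and 441 CPM in the other 11 libraries. Neutrophil markers summed to 132 CPM in GW 1 and to at most 15.2 CPM elsewhere. The hepatocyte markers, led by albumin, summed to 73000 CPM in GW 1 and to at least 99600 CPM in the others.

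The PPARα agonist alone raised genes of fatty acid handling. Acot2, a mitochondrial acyl-CoA thioesterase, rose from 4.33 ± 0.538 CPM in DMSO to 92.2 ± 10.7 CPM in GW (mean ± SD, n = 3 each), a log2 fold change of 4.40 (SE 0.16; adjusted p = 1.95e-09). Ehhadh, a bifunctional enzyme of peroxisomal β-oxidation, rose 14.6-fold, from 390 ± 49.7 to 5710 ± 901 CPM (n = 3 each), and Plin2, a lipid droplet coat protein, rose 10.6-fold, from 283 ± 31.6 to 2990 ± 156 CPM. In the opposite direction, Pck1, the gluconeogenic enzyme phosphoenolpyruvate carboxykinase, fell by 1.14 on the log2 scale (SE 0.23; adjusted p = 0.00556), from 3540 ± 167 to 1610 ± 617 CPM. Acot2 (ENSMUSG00000021226) lies on chromosome 12 from 83987861 to 83993873, Ehhadh (ENSMUSG00000022853) on chromosome 16 from 21761287 to 21787807, Plin2 (ENSMUSG00000028494) on chromosome 4 from 86648386 to 86670060 and Pck1 (ENSMUSG00000027513) on chromosome 2 from 173153048 to 173159273 (GRCm38). Acot1 to Acot5 are close paralogs, so the split of reads between them is uncertain.

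In the list of peroxisomal and microsomal fatty acid oxidation, 17 of 25 measured genes rose on GW vs DMSO, 0 fell and 8 did not pass (21 rose when adjusted over the list alone). Besides Ehhadh, Crat, carnitine acetyltransferase, rose 5.44-fold and Pex11a, a peroxisome division factor, rose 5.43-fold. The list stood above other genes by camera (adjusted p = 7.42e-18, median log2 fold change 0.99), with adjusted p = 0.228 with an estimated correlation. In mitochondrial β-oxidation and ketogenesis, 12 of 23 rose and 11 did not pass (19 rose and 1 fell when adjusted over the list alone). The carnitine transporter Slc22a5 rose 7.12-fold, the carnitine-acylcarnitine carrier Slc25a20 2.13-fold and Cpt2 1.80-fold, while Cpt1a gave a log2 fold change of 0.22 (95% interval -0.12 to 0.56) and did not pass. Camera gave this list adjusted p = 5.88e-11, and adjusted p = 0.818 with an estimated correlation. In lipid droplets and fatty acid uptake, 13 of 22 rose and 9 did not pass (16 rose when adjusted over the list alone). Acsl1, an acyl-CoA synthetase, rose 3.79-fold, Fitm2, which acts in lipid droplet formation, 2.98-fold, and Angptl4, a secreted lipoprotein lipase inhibitor, 2.93-fold. This list had adjusted p = 4.93e-13 by camera, and adjusted p = 0.193 with an estimated correlation.

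Of the fasting hormone and fuel switch genes, 7 of 14 rose and 7 did not pass (11 rose when adjusted over the list alone), with camera adjusted p = 2.54e-07, and adjusted p = 0.336 with an estimated correlation. Acot1 rose 12.8-fold, the lactate and ketone body transporter Slc16a1 3.13-fold, the pantetheinase Vnn1 2.66-fold and the transcription factor Creb3l3 1.74-fold. Pdk4, the kinase that blocks pyruvate dehydrogenase, averaged 472 ± 69.2 CPM in GW against 25.1 ± 38 CPM in DMSO (adjusted p = 0.0481). Its DMSO values were 1.75, 69.0 and 4.66 CPM, the highest in DMSO 2, the library with the most muscle marker RNA. The log2 fold change of Pdk4, GW vs DMSO, was 4.25, and 7.17 without DMSO 2 (adjusted p = 0.000206); its call was lost in each of the 11 fits that left out another library (adjusted p between 0.0611 and 0.127).

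Of 24 genes described as ERRα targets, 6 rose on GW vs DMSO (6 when adjusted over the list alone) and 18 did not pass, with camera adjusted p = 0.101. Acadm, medium-chain acyl-CoA dehydrogenase, rose 1.60-fold (adjusted p = 0.00216). Others that rose were Pdk4, Idh3a (adjusted p = 0.049), Mfn2 (adjusted p = 0.0306) and Tfam (adjusted p = 0.0147). The call of Tfam was lost without DMSO 2, DMSO 3 or GW 2 (adjusted p up to 0.0568), that of Mfn2 without DMSO 1, DMSO 3, GW 2 or GW 3 (up to 0.129) and that of Idh3a without any single library but GW 1 and GW+C29 1 (up to 0.17). Esrra itself stayed near 37.7 ± 5.93 CPM in GW and 35.0 ± 1.80 CPM in DMSO (log2 fold change 0.11, 95% interval -0.14 to 0.36, adjusted p = 0.609), and lies on chromosome 19 from 6910977 to 6921813. Ppara (chromosome 15 from 85734983 to 85802819) had 135 ± 17.1 CPM in GW and 95.5 ± 20.9 CPM in DMSO, a log2 fold change of 0.50 (SE 0.14; adjusted p = 0.0371). That call was lost without DMSO 1, DMSO 2, GW 2, GW 3, C29 1, C29 2 or GW+C29 3, with the log2 fold change of Ppara, GW vs DMSO, between 0.40 and 0.51 and adjusted p between 0.0504 and 0.146. Of 75 nuclear encoded genes of oxidative phosphorylation, 0 were called by edgeR (0 adjusted over the list alone), with a median log2 fold change of 0.02. In the citric acid cycle, 3 of 15 rose (among them Idh3a and Dlst) and 12 did not pass (3 rose and 1 fell adjusted over the list alone); the call of Dlst was lost without DMSO 1, DMSO 2 or GW 3 (adjusted p up to 0.116).

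Without both DMSO 2 and GW 1, a choice made after seeing the data, the list of ERRα targets passed on GW vs DMSO (camera adjusted p = 0.000558, median log2 fold change 0.14 against 0.06 with all libraries). So did oxidative phosphorylation (adjusted p = 0.0363, against 0.744) and the citric acid cycle (adjusted p = 0.0404, against 0.334). With an estimated correlation these 3 lists had adjusted p = 0.338, 0.947 and 0.906 in that fit. Muscle transcripts differed between the groups there, since it sets GW 2 and GW 3 (40.6 and 209 CPM of skeletal muscle markers) against DMSO 1 and DMSO 3 (1.42 and 0.466 CPM). The skeletal muscle list had a median log2 fold change of 11.54 in that fit (adjusted p = 1.78e-05, and adjusted p = 0.435 with an estimated correlation), and the mean log2 fold change of the ERRα targets was 0.74.

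Lipid synthesis genes moved in part. In lipogenesis, 5 of 19 rose and 14 did not pass (5 rose when adjusted over the list alone), with camera adjusted p = 0.175. The acetyl-CoA carboxylases Acaca and Acacb rose 1.53-fold and 3.03-fold, and Gpam, which starts glycerolipid synthesis, rose 1.80-fold. Of 25 genes of cholesterol synthesis and uptake, Hsd17b7 rose 2.64-fold (adjusted p = 5.35e-05) and 24 did not pass (1 rose adjusted over the list alone). In bile acid synthesis and transport 1 of 19 rose (Abcb4) and 2 fell (Cyp7a1 and Slco1b2), against 2 and 2 adjusted over the list alone. These calls were lost without DMSO 2, DMSO 3 or any GW library for Abcb4 (adjusted p up to 0.108), without DMSO 1, DMSO 3 or GW 1 for Slco1b2 (up to 0.112), and without any single library but DMSO 2, GW+C29 1 and GW+C29 2 for Cyp7a1 (up to 0.129). In gluconeogenesis 2 of 16 fell, Pck1 and Slc37a4 (2 adjusted over the list alone), the latter not without DMSO 3 (adjusted p = 0.0544).

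Of 29 genes of inflammation and the acute phase, 4 rose (5 when adjusted over the list alone): Il1rn, the interleukin 1 receptor antagonist, 14.9-fold (log2 fold change 3.90, and 3.28 without GW 1), Nfkbia, an inhibitor of NF-κB, 1.58-fold, and the plasma proteins Hp (adjusted p = 0.0218) and Itih4 (adjusted p = 0.0466). Both calls were lost without GW 1, the library highest in Kupffer cell and neutrophil markers (132 CPM of the latter), and without DMSO 1, DMSO 3 or GW 3 (adjusted p up to 0.0864 for Hp and 0.17 for Itih4). That of Itih4 was also lost without DMSO 2, C29 1, C29 2, C29 3 or GW+C29 1. The inflammation list had adjusted p = 0.00226 by camera. The Kupffer cell list, with 0 of 11 called over all genes and 9 rising when adjusted over the list alone, had adjusted p = 0.000923. Each had adjusted p = 0.956 with an estimated correlation. The median log2 fold change of the Kupffer list was 1.43, and 0.71 without both DMSO 2 and GW 1 (adjusted p = 0.00315, and adjusted p = 0.947 with an estimated correlation). In that fit 1 of its 11 genes rose over all genes and 3 rose when adjusted over the list alone.

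Among other lists fixed before the data were examined, Bhlhe40, a repressor of the clock, was the called member of 18 in the circadian clock (3 fell adjusted over the list alone; it fell 2-fold; list adjusted p = 0.0456, and adjusted p = 0.956 with an estimated correlation). Atg12 and Atg16l1 rose among 24 genes of autophagy and the lysosome (2 adjusted over the list alone). Of 26 nuclear receptors and coregulators, Ppara, Nrip1 and Nr1i2, the pregnane X receptor, rose and Nr5a2 fell (3 and 1 adjusted over the list alone). Gadd45b rose and Tsc22d3 fell among 12 glucocorticoid responsive genes (1 and 2 adjusted over the list alone), Atf4 and Psat1 rose among 15 of ATF4 and the unfolded protein response (2), and Myc rose among 19 of the cell cycle (0). Of these, the call of Gadd45b was lost without any DMSO library, GW 2, GW 3 or C29 3 (adjusted p up to 0.126), Tsc22d3 without any DMSO or GW library (up to 0.0712) and Atf4 without DMSO 2, DMSO 3 or GW 3 (up to 0.0802). That of Psat1 was lost without DMSO 1, DMSO 3, GW 1 or GW 3 (up to 0.093), and that of Myc without DMSO 1, DMSO 3, any GW library, C29 1, C29 2 or GW+C29 3 (up to 0.172). No member was called by edgeR, over all genes or adjusted over the list alone, among 18 genes of xenobiotic metabolism, 16 of NRF2 and oxidative stress or 7 mitochondrial genome transcripts.

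Of the cell type lists, Fabp1 rose among 9 hepatocyte markers (1 adjusted over the list alone), though not without DMSO 3 (adjusted p = 0.0556). Pck1 fell among 9 periportal markers (2) and Lgr5 fell among 10 pericentral markers (1). The lists for sinusoidal endothelial cells (11 genes), stellate cells and fibroblasts (13), cholangiocytes (6), T and NK cells (1), B cells (6), neutrophils (3), monocytes and dendritic cells (3), erythroid cells (5), adipocytes (2), mesothelial cells (1) and skeletal muscle (4) had 0 called members by edgeR, also adjusted over the list alone, and camera adjusted p of at least 0.523. Without both DMSO 2 and GW 1, skeletal muscle (adjusted p = 1.78e-05), erythroid (0.0292) and pericentral markers (0.0478) passed, with adjusted p = 0.435, 0.947 and 0.947 with an estimated correlation.

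Across all genes, edgeR called 1423 on GW vs DMSO, 790 higher and 633 lower, and 478 of them differed by at least 2-fold. The log2 fold changes of the genes with the largest falls included Clec2h at -2.87, Map2k6 at -2.8, the glycogen targeting subunit Ppp1r3c at -2.7 and Bmf at -2.67. At the other end, Acot5 was at least 21.8-fold higher in GW, with 0 counts in DMSO, and Krt79 had a count ratio of 26.6 (95% counting interval 7.13 to 224). The log2 fold change of Krt79, GW vs DMSO, was 4.63, and 7.48 without DMSO 3, the only DMSO library with counts of it. In 28.1% of genes the 3 libraries of GW did not overlap the 3 of DMSO, where chance gives 10%. Higher and lower calls were 573 and 350 without DMSO 1, 523 and 279 without DMSO 3, and 672 and 385 without GW 1. With upper quartile scaling they were 726 and 731. The count of all calls was 923 without DMSO 1 and 802 without DMSO 3, and 1196 (943 of them shared with the 1423) without both DMSO 2 and GW 1. Without both of these, a choice made after seeing the data, 18 of 25 peroxisomal genes, 12 of 23 mitochondrial, 15 of 22 lipid droplet and 8 of 15 fasting genes rose.

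**Figure D1:**
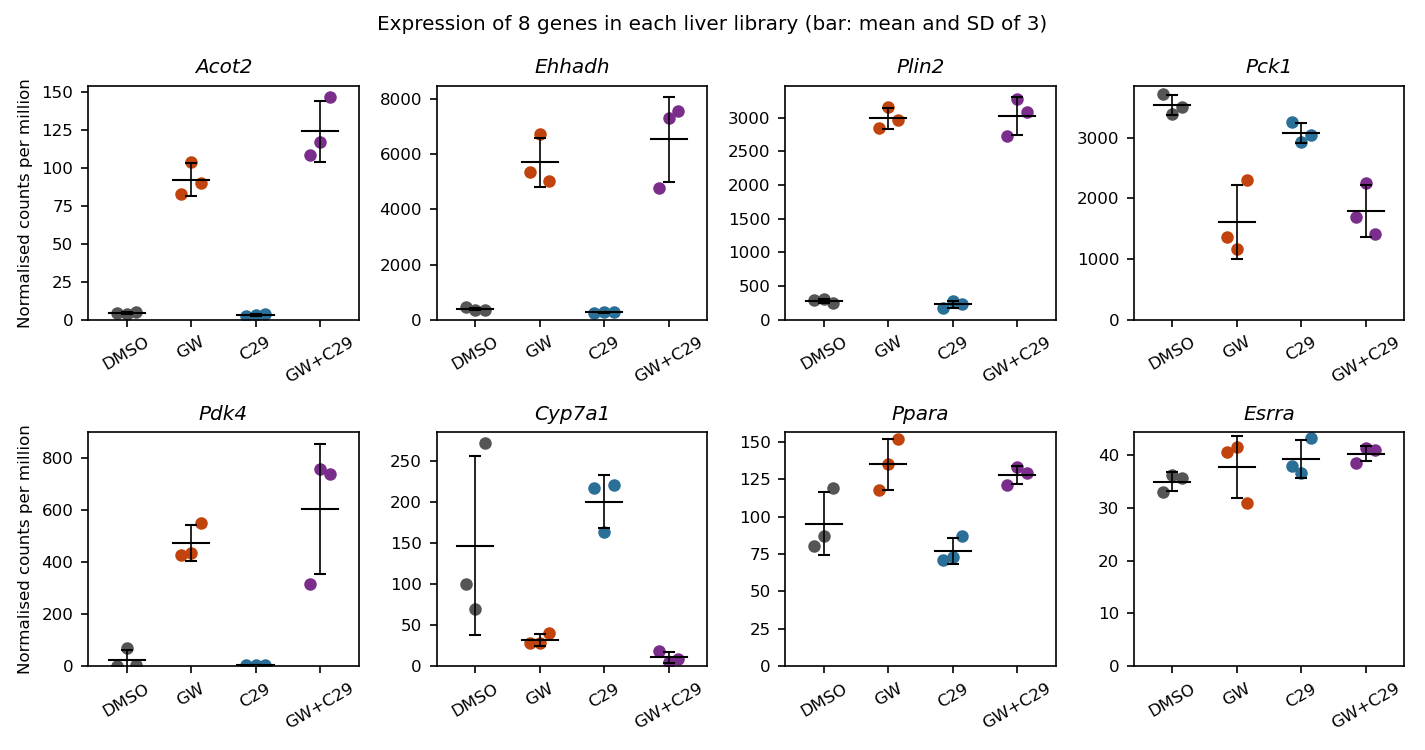
Normalised counts (CPM) of 8 genes (vertical axes, each from 0) in the 3 libraries of DMSO, GW, C29 and GW+C29 (horizontal axis); points are libraries, horizontal lines the means and error bars the SD, which the axes stop at 0. Acot2, Ehhadh and Plin2 were higher in all GW and GW+C29 libraries than in all DMSO and C29 libraries, and 1 DMSO library held Pdk4 at 69.0 CPM.

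The ERRα inverse agonist alone gave no call by edgeR. On C29 vs DMSO, edgeR called 0 of 12753 genes, with 653 at an unadjusted p below 0.05 where 638 are given by chance; DESeq2 called 3 (Angptl4, Trdn and Serpina7, all lower) and limma-voom 0. Trdn, a skeletal muscle protein, had counts in DMSO 2 but not in the other DMSO libraries or in C29. Without GW+C29 1, edgeR called 2 genes, the chaperones Hsp90aa1 and Hsph1, both lower. Esrra had 39.3 ± 3.52 CPM in C29 and 35.0 ± 1.80 CPM in DMSO (log2 fold change 0.17, 95% interval -0.08 to 0.42), and Ppara 76.9 ± 8.76 and 95.5 ± 20.9 CPM (log2 fold change -0.31, 95% interval -0.62 to 0.00; n = 3 each). Of the 24 genes described as ERRα targets, 0 were called (0 adjusted over the list alone); Acadm, for example, had a log2 fold change of -0.10 (95% interval -0.35 to 0.16). Serpina7, which encodes thyroxine-binding globulin, had the smallest p, with 13.2 ± 2.7 CPM in C29 and 28 ± 5.1 CPM in DMSO (log2 fold change -1.08, SE 0.17, adjusted p = 0.227), and was called by edgeR with no filter (adjusted p = 0.000147). Angptl4 was at 79.6 ± 8.59 CPM in C29 and 123 ± 7.25 CPM in DMSO (log2 fold change -0.63, adjusted p = 0.936) and was the called member of 22 lipid droplet genes when adjusted over the list alone. The chaperone Hspa5 was at 558 ± 90.4 and 1090 ± 154 CPM (log2 fold change -0.97, adjusted p = 0.936) and was called among 15 genes of ATF4 and the unfolded protein response when adjusted over the list alone. Serpina7, Trdn, the chaperones and these members were chosen after their values were seen.

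Camera placed the 4 fatty acid and fasting lists below other genes on C29 vs DMSO. The median log2 fold change was -0.17 in peroxisomal and microsomal fatty acid oxidation (adjusted p = 0.0022), -0.17 in mitochondrial β-oxidation (adjusted p = 7.8e-06), -0.26 in lipid droplets (adjusted p = 9.51e-05) and -0.30 in fasting genes (adjusted p = 0.0301). With an estimated correlation the adjusted p was 0.719 for lipid droplets and 0.956 for the other 3 lists. Without both DMSO 2, the library richest in muscle markers, and GW 1, the call of the fasting list was lost (median -0.14, adjusted p = 0.314) and lipid droplets had a median of -0.18 (adjusted p = 0.0478, and adjusted p = 0.947 with an estimated correlation). Peroxisomal and microsomal fatty acid oxidation (median -0.16, adjusted p = 0.000814) and mitochondrial β-oxidation (-0.17, adjusted p = 1.2e-06) still passed, with adjusted p = 0.947 and 0.906 with an estimated correlation. By the self-contained test fry none of the 4 lists passed on C29 vs DMSO in that fit, which was chosen after seeing the data. Fry values of the fit with all libraries are not given here. Its adjusted p was 0.583 for peroxisomal genes, 0.373 for mitochondrial β-oxidation, 0.733 for lipid droplets and 0.936 for fasting genes. For the same lists and fit, fry gave adjusted p of at most 0.0047 on GW vs DMSO and 0.000942 on GW+C29 vs C29. Pdk4, a member of the fasting list, had a log2 fold change of -2.64 on C29 vs DMSO, and 0.27 without DMSO 2. The groups did not overlap in 12.4% of genes, where chance gives 10%. In counts simulated once for this comparison over 12599 genes, 20.9% of 67 genes changed 1.5-fold, 64.2% of 67 changed 2-fold and 89.4% of 66 changed 4-fold were called. So were 9 unchanged genes. The recovery holds for the number of changed genes simulated and can be lower where fewer genes change.

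With both compounds, genes of the fatty acid and fasting lists rose over DMSO. On GW+C29 vs DMSO, Acot2 rose 28.4-fold to 124 ± 20.4 CPM, Ehhadh 16.8-fold to 6550 ± 1540 CPM and Plin2 10.7-fold to 3030 ± 282 CPM (n = 3 each; largest adjusted p = 5.58e-08). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell from 147 ± 109 to 10.7 ± 6.91 CPM (log2 fold change -3.74, adjusted p = 0.00595; -2.94 without DMSO 3 and -4.43 without GW+C29 1), Tsc22d3, a glucocorticoid target, fell 3.34-fold and Smpd3 fell 11.3-fold. In peroxisomal and microsomal fatty acid oxidation 19 of 25 genes rose and 6 did not pass (22 rose adjusted over the list alone), in mitochondrial β-oxidation 16 of 23 (19; 10 rose without GW+C29 2 or GW+C29 3), in lipid droplets 13 of 22 (15) and in fasting genes 9 of 14 (10). By camera these had adjusted p = 4.96e-20, 1.86e-14, 1.23e-14 and 8.51e-08, and adjusted p = 0.193, 0.595, 0.193 and 0.321 with an estimated correlation. Of the genes described as ERRα targets, 5 of 24 rose (7 adjusted over the list alone), among them Acadm 1.78-fold, Tfam 1.5-fold, Idh3a 1.40-fold and Pdk4 24.4-fold; the list had adjusted p = 0.0165, and adjusted p = 0.956 with an estimated correlation. The call of Idh3a was lost without DMSO 1, GW+C29 2 or GW+C29 3 (adjusted p up to 0.0659), and that of Pdk4 without any single library but DMSO 2 and GW+C29 1 (up to 0.101). The log2 fold change of Pdk4 was 4.61, and 7.53 without DMSO 2 (adjusted p = 0.000165), the DMSO library that held 69.0 CPM of it. Of 75 oxidative phosphorylation genes, 0 were called by edgeR (0 adjusted over the list alone), with a median log2 fold change of 0.15 (camera adjusted p = 8.98e-06, and adjusted p = 0.956 with an estimated correlation).

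In total 1395 genes were called by edgeR on GW+C29 vs DMSO, 792 higher and 603 lower, and 29% of genes did not overlap between the groups (10% by chance). The count was 822 without DMSO 3 (551 higher and 271 lower), 801 without GW+C29 2 (533 and 268) and 805 without GW+C29 3 (524 and 281). With upper quartile scaling 720 were higher and 695 lower. GW vs DMSO and GW+C29 vs DMSO shared 614 higher calls, where independent lists would share 49.1, and 391 lower calls (29.9 for independent lists). Across genes their log2 fold changes had a Pearson correlation of 0.663 and a covariance of 0.293. In 20 simulations of unchanged groups set against the same controls these were 0.151 ± 0.064 (SD) and 0.014. The simulated groups were drawn around the mean of these same DMSO libraries, so the error of that mean is left out. That error is what the 2 comparisons share, so the simulated values are no baseline for shared controls. Genes are not independent replicates, the 3 DMSO libraries are too few to split, and part of the excess overlap may come from them. For GW vs DMSO and C29 vs DMSO, which share the same controls and have 0 calls in common, the correlation was 0.165 and the covariance 0.047. Whether these exceed what the shared DMSO libraries alone would give cannot be read from this simulation.

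**Figure D2:**
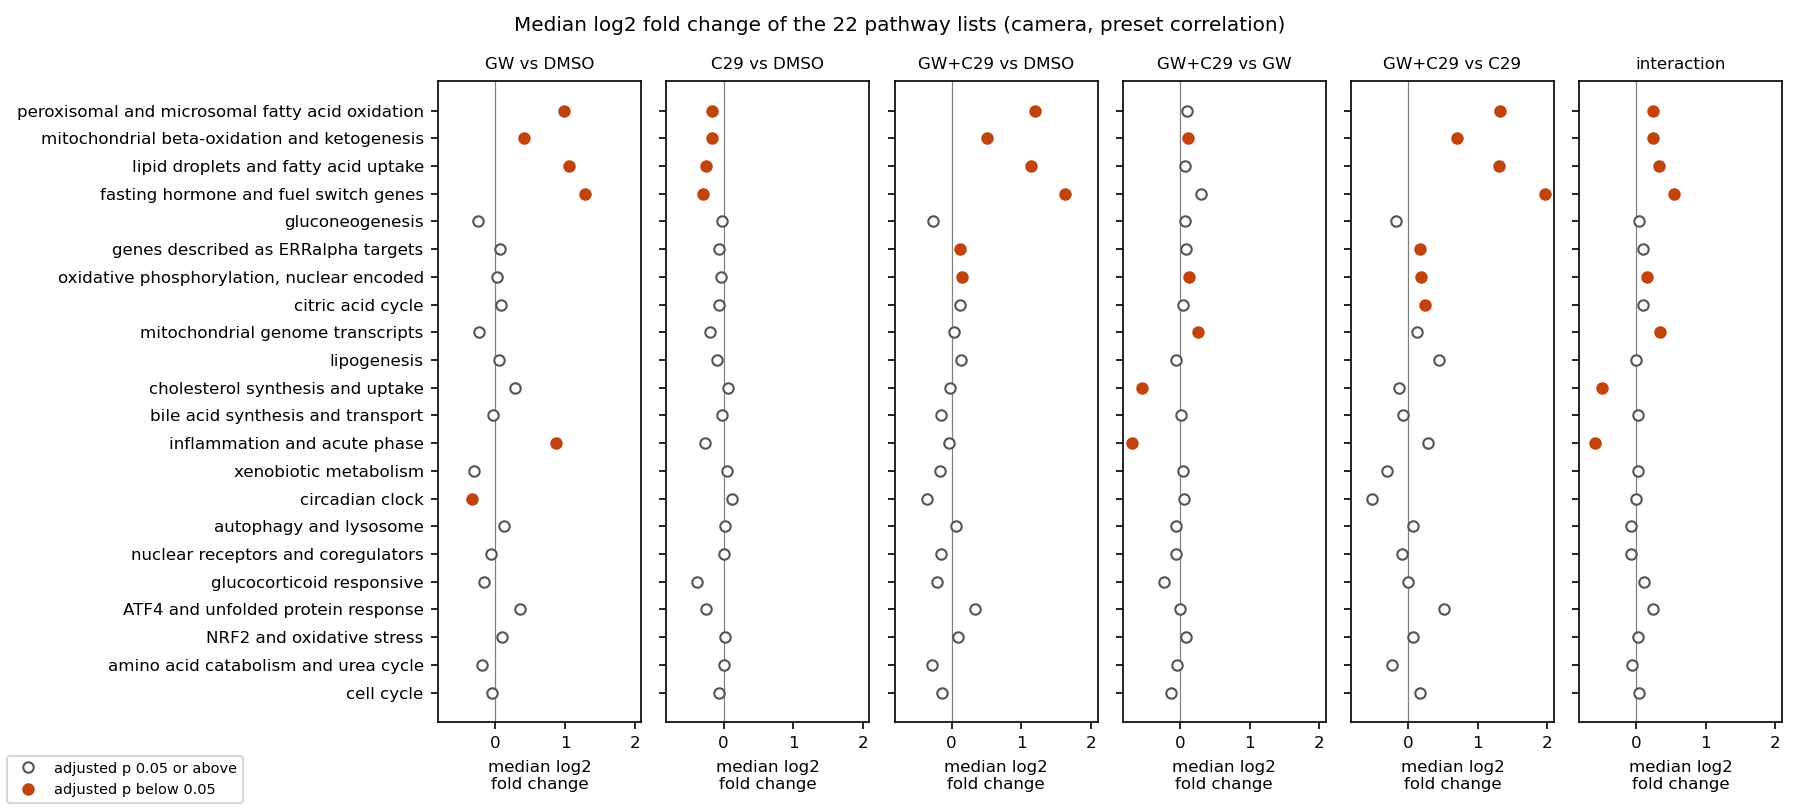
Median log2 fold change (horizontal axes) of each of the 22 pathway lists (vertical axis) in the 6 comparisons; filled points have a camera adjusted p below 0.05 with the preset correlation and open points do not. The 4 fatty acid and fasting lists lay above 0 in the 3 comparisons of GW with a group lacking it; with an estimated correlation 0 of the 222 tests passed.

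Adding C29 to GW gave no call by edgeR. On GW+C29 vs GW, edgeR called 0 genes (676 at an unadjusted p below 0.05, 638 by chance; smallest adjusted p = 0.896), limma-voom 0 and DESeq2 20, of which 1 was higher and 19 lower. Esrra had 40.3 ± 1.49 CPM in GW+C29 and 37.7 ± 5.93 CPM in GW (log2 fold change 0.10, 95% interval -0.15 to 0.34; -0.03 without GW 3) and Ppara 128 ± 6.28 and 135 ± 17.1 CPM (log2 fold change -0.08, 95% interval -0.39 to 0.22; 0.01 without GW 3). Acadm (log2 fold change 0.15, 95% interval -0.11 to 0.41) did not pass. Of the 24 genes described as ERRα targets, 0 were called (0 adjusted over the list alone); the median log2 fold change was 0.09 and the mean -0.14, which differ in sign. Without both DMSO 2 and GW 1, a choice made after seeing the data, 1 fell (2 adjusted over the list alone). The median was then 0.006 and the mean -0.243. The GW group of that fit is GW 2 and GW 3, with 40.6 and 209 CPM of skeletal muscle markers, and the cause was not tested.

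By camera with the preset correlation, oxidative phosphorylation lay higher in GW+C29 than in GW (median log2 fold change 0.14, adjusted p = 1.72e-12), as did mitochondrial genome transcripts (0.26, adjusted p = 0.00749) and mitochondrial β-oxidation (0.12, adjusted p = 0.00156). Cholesterol synthesis (median -0.54, adjusted p = 4.03e-08), inflammation and the acute phase (-0.69, adjusted p = 9.33e-07), Kupffer cell markers (-1.17, adjusted p = 3.12e-06) and skeletal muscle markers (-9.96, adjusted p = 0.0165) lay lower. Each of these 7 lists had adjusted p = 0.956 with an estimated correlation and 0 called members, and they were compared with a GW group in which GW 1 held 1410 CPM of Kupffer markers and GW 3 held 209 CPM of muscle markers. GW 1 also had the lowest share of mitochondrial genome counts, 3.82%. Without both DMSO 2 and GW 1 the calls of mitochondrial genome transcripts (median 0.11, adjusted p = 0.428) and mitochondrial β-oxidation (0.05, adjusted p = 0.575) were lost. Oxidative phosphorylation (median 0.10, adjusted p = 5.17e-05) and cholesterol synthesis (-0.63, adjusted p = 1.49e-08) still passed, each with adjusted p = 0.947 with an estimated correlation, and skeletal muscle had a median of -10.54 (adjusted p = 4.11e-14, and adjusted p = 0.211 with an estimated correlation). The medians of Kupffer cell markers and inflammation were -0.26 (adjusted p = 0.0421) and -0.39 (adjusted p = 0.0205) in that fit, each with adjusted p = 0.947 with an estimated correlation.

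The groups GW+C29 and GW did not overlap in 8.63% of genes, where chance gives 10%. The fit without GW 2 keeps GW 1 and GW 3 in the GW group. Their mean-centred log2 CPM of the inflammation list was 1.76 and 0.87, against -0.46 in GW 2. GW 1 also held 1410 CPM of Kupffer markers. In that fit edgeR called 6 genes lower: the interferon-induced Zbp1, Gbp2 and Parp14, Alpk1, Gas6 and a predicted gene. Without GW+C29 1 it called Nsdhl, an enzyme of cholesterol synthesis, and without both DMSO 2 and GW 1 it called 21 genes, all lower; these genes were singled out after their values were seen. The latter fit leaves in the GW group only GW 2 and GW 3, with 40.6 and 209 CPM of skeletal muscle markers against 0.766 to 1.3 CPM in the GW+C29 libraries. In it, 1 of 4 members of the skeletal muscle list was called lower (4 when adjusted over the list alone), with a median log2 fold change of -10.54 (camera adjusted p = 4.11e-14, and adjusted p = 0.211 with an estimated correlation).

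Whether genes responded to GW in the presence of C29 was read from GW+C29 vs C29. Acot2 rose 40.6-fold, from 3.05 ± 0.473 to 124 ± 20.4 CPM (n = 3 each; adjusted p = 2.13e-10), Acot1 25.6-fold, Ehhadh 24.9-fold and Plin2 13.3-fold. Pdk4 rose from 3.99 ± 1.27 to 605 ± 250 CPM (log2 fold change 7.25, SE 1.34, adjusted p = 0.00909) and Ppara from 76.9 ± 8.76 to 128 ± 6.28 CPM (log2 fold change 0.73, SE 0.14, adjusted p = 0.00416). Cyp7a1 fell 18.2-fold, from 200 ± 32.3 to 10.7 ± 6.91 CPM (log2 fold change -4.18, adjusted p = 0.00314; -4.88 without GW+C29 1), Cux2 fell 19.5-fold (log2 fold change -4.28, and -4.89 without GW+C29 2), and the glucocorticoid target Tsc22d3 fell 2.76-fold. Esrra had a log2 fold change of 0.04 (95% interval -0.21 to 0.29), which was -0.01 with upper quartile scaling and without C29 2.

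In peroxisomal and microsomal fatty acid oxidation 20 of 25 genes rose and 5 did not pass (22 rose adjusted over the list alone), in mitochondrial β-oxidation 19 of 23 (21), in lipid droplets 17 of 22 (18) and in fasting genes 9 of 14 (11). Eci1, an enoyl-CoA isomerase, rose 2.06-fold, Acsl1 5.68-fold and Vnn1 4.40-fold. Camera gave adjusted p = 4.68e-21, 2.4e-18, 9.02e-18 and 5.56e-09, and adjusted p = 0.193, 0.372, 0.193 and 0.247 with an estimated correlation. Of the genes described as ERRα targets 8 of 24 rose (8 adjusted over the list alone), including cytochrome c (Cycs, 1.61-fold), Acadm (1.90-fold) and Tfam (1.46-fold), whose calls held in each fit that left out 1 library. The list had adjusted p = 0.00262, and adjusted p = 0.956 with an estimated correlation. Of 75 oxidative phosphorylation genes 4 rose (Cycs, Ndufb3, Atp5g3 and Atp5k) and 71 did not pass (2 rose adjusted over the list alone; camera adjusted p = 5.76e-07), and of 15 citric acid cycle genes 4 rose (among them Cs, Idh3a and Dlst; 4 adjusted over the list alone; camera adjusted p = 0.00827). For both lists the adjusted p was 0.956 with an estimated correlation. The calls of Ndufb3 and Atp5g3 were lost without any C29 library or GW+C29 3, and without GW+C29 1 or GW+C29 2 respectively (adjusted p up to 0.127 and 0.0939), and that of Atp5k without C29 1 or C29 3 (up to 0.068). That of Cs was lost without DMSO 1, DMSO 3 or any C29 or GW+C29 library (up to 0.18), that of Idh3a without DMSO 3, any C29 library, GW+C29 2 or GW+C29 3 (up to 0.168) and that of Dlst without C29 1, C29 2 or GW+C29 2 (up to 0.0836).

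In lipogenesis 7 of 19 genes rose on GW+C29 vs C29 (7 adjusted over the list alone; camera adjusted p = 0.0617, and 0.0431 without both DMSO 2 and GW 1, where the estimated correlation gave adjusted p = 0.947), among them Acacb 3.34-fold and Elovl5, a fatty acid elongase, 1.94-fold. In the circadian clock 4 of 18 fell (among them Per2, Cry2 and Tef) and Clock rose (5 and 1 adjusted over the list alone). Per2, Cry2 and Tef lost their calls without C29 1, C29 3, GW+C29 2 or GW+C29 3 (adjusted p up to 0.13). Clock lost its call without any DMSO library, GW 2 or those same 4 libraries (up to 0.177). In amino acid catabolism and the urea cycle 3 of 23 fell, the urea cycle activator Nags, Hal and Prodh, and 2 rose, Tdo2 and Aass (3 and 2 adjusted over the list alone). Hal lost its call without C29 3 or GW+C29 3 (adjusted p up to 0.0574), Tdo2 without C29 2, C29 3, GW+C29 2 or GW+C29 3 (up to 0.0705) and Aass without any C29 library (up to 0.0702).

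Across all genes edgeR called 1803 on GW+C29 vs C29, 950 higher and 853 lower, and with upper quartile scaling 797 higher and 1076 lower. In 34.1% of genes the groups did not overlap (10% by chance). The count was 1058 without C29 1, 1027 without C29 3, 982 without GW+C29 2 and 1051 without GW+C29 3. Higher and lower calls were 603 and 455, 614 and 413, 612 and 370, and 612 and 439 in turn.

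The responses to GW without and with C29 share no library and could be set against each other. Of the 1423 genes called on GW vs DMSO, 1395 (98%) had the same direction on GW+C29 vs C29, with a slope of 0.901 across genes (Pearson correlation 0.93, Spearman correlation 0.929). Over the 1803 genes called on GW+C29 vs C29 instead, 98.6% had the same direction and the slope was 1.107. The slope thus lay below or above 1 depending on which comparison chose the genes. Over all 12753 genes, 73.1% had the same direction and the slope was 0.724 (Pearson correlation 0.708, Spearman correlation 0.634). Both comparisons called 598 genes higher, where independent lists would share 58.8, and 396 lower, where they would share 42.3. Over the 84 genes of the 4 fatty acid and fasting lists, 78 had the same direction and the slope was 1.065. Of 995 genes called in both, Serpina7 alone had opposite directions: it fell on GW vs DMSO (log2 fold change -0.64, adjusted p = 0.0238; lost without DMSO 1, GW 1 or GW 3, with adjusted p up to 0.118) and rose on GW+C29 vs C29 (0.88, adjusted p = 0.00363). With 1 library left out, the slope ranged from 0.70 without GW 2 to 0.956 without GW+C29 1 (jackknife SE 0.207). In every such fit the genes were those called on GW vs DMSO in that fit, so the spread also holds the change of genes. Called in the same way, the genes gave a slope of 0.279 without both DMSO 2 and GW 1 (Spearman correlation 0.782, 95.5% of 1196 genes in the same direction). That fit sets GW 2 and GW 3, with 40.6 and 209 CPM of skeletal muscle markers, against DMSO 1 and DMSO 3, with 1.42 and 0.466 CPM, and the muscle list had a median log2 fold change of 11.54 on GW vs DMSO and -15.73 in the interaction (adjusted p = 1.42e-12, and adjusted p = 0.217 with an estimated correlation). Without both DMSO 2 and GW 3 the slope was 0.818 (98.8% of 935 genes in the same direction), and 0.85 with the muscle list as a covariate.

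The test of the difference between these responses, the interaction, called 0 of 12753 genes by edgeR (471 at an unadjusted p below 0.05, 638 by chance; smallest adjusted p = 0.216, Serpina7). DESeq2 called 1 gene, Serpina7, as did edgeR with no filter (adjusted p = 0.000114), and limma-voom 0. Without GW+C29 1, edgeR called 1 gene, Nsdhl. Within the 1423 genes called on GW vs DMSO, 113 had an unadjusted interaction p below 0.05, where chance gives 71.2. Adjusted over these genes alone, 1 was called by edgeR (adjusted p = 0.0242). They were chosen on GW vs DMSO, whose libraries also enter the interaction, so 71.2 is no baseline for them. In the single simulation for the interaction over 12591 genes, 4.48% of 67 genes changed 1.5-fold, 34.3% of 67 changed 2-fold and 71.2% of 66 changed 4-fold were called. So were 7 unchanged genes. Here too, recovery can be lower where fewer genes change than were simulated. Acot2 (log2 difference 0.95, 95% interval 0.45 to 1.44, adjusted p = 0.983) and Acot1 (1, 95% interval 0.42 to 1.59, adjusted p = 0.983) were called when adjusted over their lists alone. They are the called members of 23 mitochondrial β-oxidation and 14 fasting genes. Ppara had a log2 difference of 0.23 (95% interval -0.21 to 0.66) and Esrra of -0.07 (95% interval -0.43 to 0.28; 0 without GW 2 or C29 3).

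**Figure D3:**
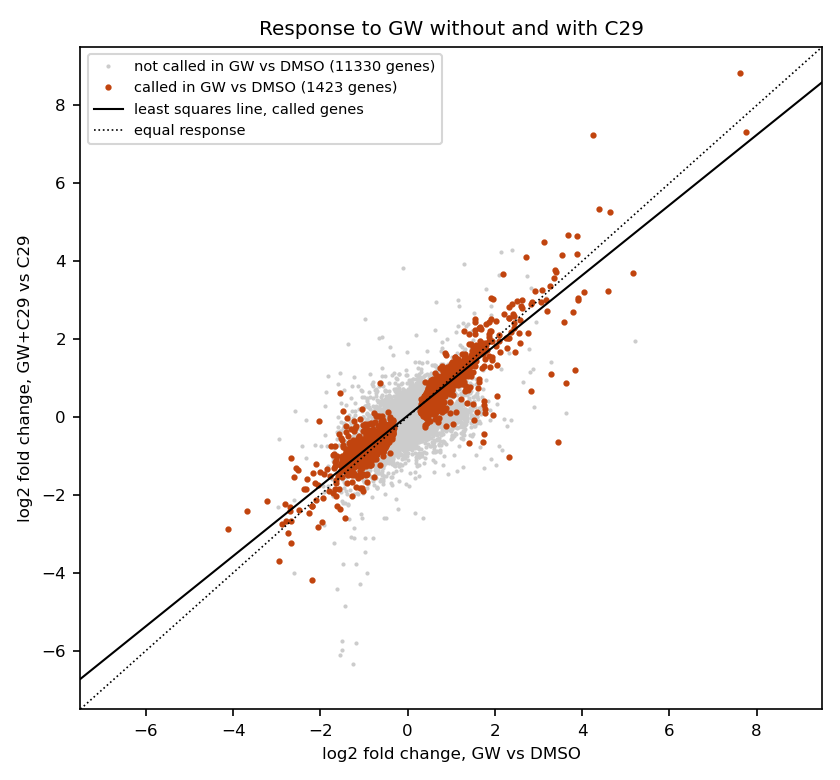
Log2 fold change on GW vs DMSO (horizontal axis) against that on GW+C29 vs C29 (vertical axis) for the 12753 genes tested, with the 1423 genes called on GW vs DMSO in colour, their least squares line (slope 0.901) and a dotted line of equal response. Nearly all coloured points (1395 of 1423) lie in the quadrants of shared direction.

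The response to C29 could be compared without and with GW only over all genes tested, because 0 genes were called on C29 vs DMSO. Of 12753 genes, 52.7% had the same direction on C29 vs DMSO and GW+C29 vs GW, against 73.1% for the GW responses over the same genes. The slope was 0.766 with a Pearson correlation of 0.647 and a Spearman correlation of 0.109 across genes. Without DMSO 2, the library with 467 CPM of muscle markers, the slope was -0.473 and the Pearson correlation -0.332. Without GW 3 the slope was 0.475, and with C29 1, C29 2, C29 3 or another library left out it was between 0.614 and 0.793 (jackknife SE over all libraries 1.07).

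**Figure D4:**
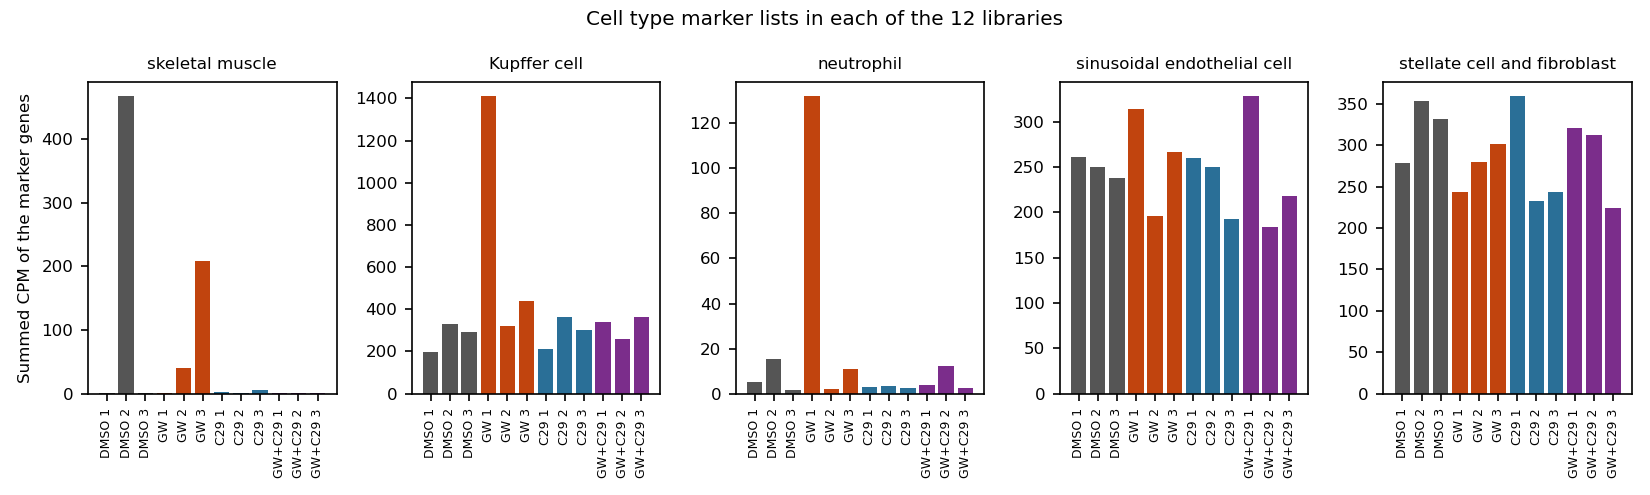
Summed CPM (vertical axes, from 0) of the marker genes of skeletal muscle, Kupffer cells, neutrophils, sinusoidal endothelial cells and stellate cells in each of the 12 libraries (bars, coloured by group). DMSO 2 (467 CPM) and GW 3 (209 CPM) hold the highest muscle levels, and GW 1 the highest Kupffer (1410 CPM) and neutrophil (132 CPM) levels.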

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

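The tests of muscle RNA and of GW 1 in this part, the fits without DMSO 2 and GW 1 or without DMSO 2 and GW 3, and the fit with a muscle covariate were chosen only after the result was seen, whereas the bounds for the correlation of the C29 responses and the other splits were set before their values were known.

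In 9 lists the interaction test of camera passed with the preset correlation. With an estimated correlation 0 of them passed (adjusted p = 0.719 for lipid droplets and 0.956 for the other 8), so a difference in the response to GW with and without C29 rests on the preset correlation. The lists with a more positive response in the presence of C29 were oxidative phosphorylation (adjusted p = 5.2e-10, median log2 difference 0.16), mitochondrial β-oxidation (8.45e-09, 0.25), lipid droplets (7.09e-05, 0.32), peroxisomal and microsomal fatty acid oxidation (0.000261, 0.24), mitochondrial genome transcripts (0.000518, 0.35) and fasting genes (0.0121, 0.54). Those with a more negative response were cholesterol synthesis (2.28e-06, -0.49), Kupffer cell markers (0.000134, -1.31) and inflammation and the acute phase (0.00935, -0.59). By gene, edgeR called 0 genes in the interaction (471 at an unadjusted p below 0.05; DESeq2 called 1 and limma-voom 0). Without DMSO 2 and GW 1, the adjusted p by camera with the preset correlation is given with the median difference. It was 0.00422 for oxidative phosphorylation (0.07), 2.94e-05 for mitochondrial β-oxidation (0.17), 0.0471 for lipid droplets (0.22) and 0.0105 for peroxisomal genes (0.16). For cholesterol synthesis it was 1.72e-05 (-0.60), for Kupffer cell markers 0.00148 (-0.48) and for inflammation 0.00207 (-0.53). Mitochondrial genome transcripts (adjusted p = 0.182) and fasting genes (0.388) did not pass in that fit, while skeletal muscle markers (1.42e-12) and the cell cycle (0.0386) did. With an estimated correlation the adjusted p there was 0.217 for muscle, 0.435 for the cell cycle and 0.947 for the other lists named. The estimates ran from 0.13 for lipid droplets to 0.834 for mitochondrial genome transcripts over the 9 lists, against the preset of 0.01. If members correlate that strongly, p-values with the preset are too small. In the interaction of that fit, the self-contained test fry gave adjusted p of 0.489 to 0.936 for the 8 lists other than Kupffer cell markers. The interaction also equals GW+C29 vs GW minus C29 vs DMSO, so a list lower on C29 alone can give a positive difference. In that fit the medians on C29 vs DMSO and GW+C29 vs GW were -0.16 and 0.01 for peroxisomal genes. They were -0.17 and 0.05 for mitochondrial β-oxidation, -0.18 and 0.03 for lipid droplets, and -0.004 and 0.095 for oxidative phosphorylation.

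Skeletal muscle markers summed to 467 CPM in DMSO 2, 209 CPM in GW 3 and 40.6 CPM in GW 2. A level set by treatment is argued against, since the highest DMSO library held 1000 times the lowest. RNA of skeletal muscle in the tissue taken is a candidate explanation: of 16 further muscle genes, 15 (93.8%) were at least 10 times higher in DMSO 2 than in DMSO 1 and DMSO 3, among them Myh1 at 234 CPM, Ttn at 177 CPM and Atp2a1 at 174 CPM in DMSO 2. The exception was Neb, 7.79 times higher, which the other libraries also expressed. When in the procedure such RNA entered is open.

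In GW 1, Kupffer markers were 3.69 times, monocyte markers 3.4 times and neutrophil markers 20.2 times the mean of GW 2 and GW 3. Stellate markers, at 0.838 times that mean, and sinusoidal endothelial markers, at 1.36 times, argue against a general rise of non-hepatocyte cells. The hepatocyte markers were at 0.67 times that mean. Whether added immune cells lowered the share of hepatocytes cannot be decided by stellate and endothelial markers, which need not rise with them. A few genes taking most of the counts is argued against by the 10 most abundant genes. They held 15.52% of counts in GW 1, the lowest of the 12 libraries. A response to GW stays open for the neutrophil markers, 132 CPM in GW 1: the highest of the other 5 libraries with GW, GW+C29 2, held 0.815 times the highest DMSO library, DMSO 2 (12.4 and 15.2 CPM), but it and GW 3 (10.8 CPM) lay above DMSO 1 (5.35 CPM) and DMSO 3 (1.77 CPM). It stays open for the other parts too, since without GW 1 the median log2 fold change on GW vs DMSO was 0.45 for the Kupffer list (323 CPM in GW 2 and 441 CPM in GW 3, against 196 to 332 CPM in DMSO) and 0.42 for the inflammation and acute phase list, between the bounds of 0.5 for and 0.1 against it. An inflammatory state of this 1 mouse may also account for the pattern, and was not tested.

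The log2 fold changes of C29 without and with GW had a Pearson correlation of 0.647 across genes. Muscle RNA in DMSO 2, GW 2 and GW 3 is a candidate explanation, since the correlation was 0.172 with the muscle list as a covariate, close to the bound of 0.2 set for it, and -0.332 without DMSO 2. A shared response to C29 was to be set aside if the Spearman correlation without DMSO 2 and GW 3 was 0.05 or lower, and it was -0.078. The jackknife SE of 0.212, that of the Spearman correlation over all 12 libraries with 1 left out at a time, exceeds the distance to that bound, and this allowance for spread was added after the value was seen. A shared response to C29 therefore cannot be told apart from its absence with these 12 libraries.

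For comparisons of 3 against 3 libraries there are 10 splits, too few for a share below 0.05. The real counts and the highest of the other splits were 1423 and 1 for GW vs DMSO, 0 and 0 for C29 vs DMSO, 1395 and 0 for GW+C29 vs DMSO, 0 and 3 for GW+C29 vs GW, and 1803 and 0 for GW+C29 vs C29. The number of splits with as many genes, the real one included, was 1, 10, 1, 10 and 1 in turn. For the interaction, the real count by edgeR was 0, which any split reaches, so that 100 of 100 splits say nothing about chance; the same holds for the other 2 comparisons with a count of 0. Of the other splits for the interaction 2 called genes, 25 and 16, and what these splits share was not tested.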

How the results depend on the processing

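The fits without both DMSO 2 and GW 1, without both DMSO 2 and GW 3, and with the muscle list as a covariate were chosen only after the result was seen; the other alternatives were planned.

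With RLE scaling, upper quartile scaling, DESeq2, limma-voom, no filter and the stricter filter, the genes called numbered 1341 to 1618 on GW vs DMSO, 1231 to 1549 on GW+C29 vs DMSO and 1649 to 1925 on GW+C29 vs C29. With the replicate block they were 1336, 1288 and 1718, of which 1252, 1221 and 1615 were shared with the counts reported; in 18 pairs of libraries with the same number, r was -0.33 to 0.22, so the numbers were not taken to pair mice. With only the groups compared the counts were 877, 1136 and 1870; both the libraries and the genes tested change there, and the cause was not tested. Lane 1 alone, with fewer reads and 10388 genes tested, gave 823, 816 and 1061, and leaving out DMSO 2 and GW 3 gave 935 on GW vs DMSO. Leaving out 1 library gave 802 (without DMSO 3) to 1469 (without GW+C29 1) on GW vs DMSO, 801 (without GW+C29 2) to 1509 (without GW 1) on GW+C29 vs DMSO, and 982 (without GW+C29 2) to 1986 (without GW+C29 1) on GW+C29 vs C29. It was also 923 without DMSO 1 for GW vs DMSO, 822 without DMSO 3 and 805 without GW+C29 3 for GW+C29 vs DMSO, and 1058, 1027 and 1051 without C29 1, C29 3 and GW+C29 3 for GW+C29 vs C29.

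The counts of 0 by edgeR (653, 676 and 471 genes at an unadjusted p below 0.05; limma-voom 0 in each) moved in few alternatives. On C29 vs DMSO DESeq2 called 3 and no filter 1 (Serpina7), and leaving out 1 library gave 0 to 2 (2 without GW+C29 1). On GW+C29 vs GW DESeq2 called 20 and the fit without DMSO 2 and GW 1 called 21, and leaving out 1 library gave 0 to 6 (6 without GW 2, 1 without GW+C29 1). In the interaction DESeq2 and no filter each called 1 (Serpina7), and leaving out 1 library gave 0 to 1 (1 without GW+C29 1). The cause was not tested. Of 222 list tests, 40 passed with the preset and 0 with an estimated correlation. Without DMSO 2 and GW 1, 50 passed with the preset; besides those given elsewhere, Kupffer cell (adjusted p = 0.0413) and B cell markers (0.0404) newly passed on C29 vs DMSO, the citric acid cycle (0.0404) and pericentral markers (0.0287) on GW+C29 vs DMSO, and the cell cycle (0.0363) and erythroid markers (0.0296) on GW+C29 vs GW, with adjusted p of 0.435 to 0.947 with an estimated correlation. Of 23 mitochondrial β-oxidation genes, 7 rose on GW vs DMSO without DMSO 2 and GW 3.

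The slope of the GW responses, 0.901, was 0.279 without DMSO 2 and GW 1, a fit that sets the muscle-rich GW 2 and GW 3 against DMSO 1 and DMSO 3, 0.818 without DMSO 2 and GW 3 and 0.85 with the muscle covariate; the cause was not tested. The slope of the C29 responses, 0.766, was -0.473 (without DMSO 2) to 0.793 (without GW 1) with 1 library left out, -0.39 without DMSO 2 and GW 1 and -0.31 without DMSO 2 and GW 3, fits that share the absence of the library richest in muscle RNA.

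For the genes the naming rule takes and the others named, 4831 of 5472 values kept direction and side of the threshold, 617 no longer passed, 9 newly passed and 15 reversed; DESeq2 gave no adjusted p for 4 values of Pdk4, which are not counted. Among the reversed, the log2 fold change of Esrra, GW vs DMSO, was -0.09 with lane 1 alone. That of Esrra, GW+C29 vs C29, was -0.01 with upper quartile scaling and -0.01 (without C29 2) to 0.11 with 1 library left out. That of Esrra, interaction, was 0.35 with lane 1 alone and -0.20 to 0 (without GW 2 or C29 3). On GW+C29 vs GW, Esrra was -0.03 and Ppara 0.01 without DMSO 2 and GW 3, with 1 library left out Esrra -0.03 (without GW 3) to 0.17 and Ppara -0.17 to 0.01 (without GW 3). On C29 vs DMSO, Pdk4 was -3.2 to 0.27 (without DMSO 2) and 0.27 in both fits without 2 libraries, and Trdn was -9.25 to 0 (without DMSO 2) and 0 without DMSO 2 and GW 1. None of these reversed values had passed the threshold, and the cause was not tested.

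In simulated counts 20.9% of 67 genes changed 1.5-fold were called on C29 vs DMSO. In the interaction 4.48% of 67 genes changed 1.5-fold and 34.3% of 67 changed 2-fold were called. This recovery reflects 3 mice per group, their spread, depth and the number of changed genes simulated, which were not varied apart. The adjustment of p-values is stricter where fewer genes change, so recovery can be lower in a comparison with fewer changed genes.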

Other observations

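No test was run for this part; Serpina7 was chosen only after the result was seen.

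Serpina7 had 33.8, 24.5 and 25.6 CPM in DMSO, 16.4, 19.7 and 17.8 CPM in GW, 13.4, 10.4 and 15.8 CPM in C29, and 23.5, 28.2 and 21.3 CPM in GW+C29. In the interaction it was not called by edgeR with the filter used (adjusted p = 0.216), and was called with no filter (adjusted p = 0.000114) and by DESeq2. RLE scaling, upper quartile scaling, limma-voom and the stricter filter called 0 genes there. The fit with no filter tests 24513 genes and estimates their spread anew, and why its adjusted p differs was not tested.

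Fbf1 was at 447 ± 121 CPM in GW and 30.5 ± 21.8 CPM in DMSO, a log2 fold change of 3.88 (SE 0.60; adjusted p = 0.00409), and 4.62 without DMSO 2.

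Principal components of log2 CPM held 35.4%, 19.6%, 11.7% and 6.9% of the variance. On component 1 the 6 libraries with GW lay between 13 and 34.5 and the 6 without it between -35.6 and -9. DMSO 2 lay at -55.7 on component 2 and GW 1 at -46.2 on component 3.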
